A study of Mus musculus with 26 samples.

How the data were processed

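Micro-C libraries were made by the authors from mouse RAD21-dTAG ESCs in G1 and from EpiLCs, in the 5 groups of 26 libraries given by the labels. Per the submitters' processing notes, reads were aligned with BWA 0.7.17 and processed with Juicer 1.22.01 on mm10. The processed data used here are a list of boundary intervals from the pooled DMSO-treated ESC libraries, with chromosome, start and end and no score. The boundary caller, its window and its threshold are not given in the sources used here. Contact depth per library is unknown, no sample has values of its own in that list, and the other 4 groups were not analysed here.

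All 3515 intervals were checked to be 25 kb wide. Positions are printed counted from 1. A domain is the stretch between neighbouring boundaries of a chromosome. Genes came from the RefSeq annotation of GRCm38.p6, the build also called mm10. Some genes of unplaced, alternate or patch scaffolds carry a chromosome name there but positions counted along the scaffold. These 345 genes, 110 of them protein-coding, were recognised by their place after each chromosome's sorted genes and left out, which kept 49209 genes, 21521 of them protein-coding. This filter was added after the first results had been seen, when genes appeared in the unsequenced first bases of chromosomes, and it changed no list's side of the threshold in the rotation test.

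Gene family lists, such as the ribosomal, proteasome, Eif, Zfp and receptor genes, were made by symbol pattern and hold every protein-coding gene that matches it, and RNA gene lists by annotated class. The tests, the 24 gene lists and most alternatives were chosen before the data were examined. The annotation has no strand, so the planned start site was replaced by either end of the gene. A gene counted as near a boundary when an end lay inside the interval or within 10 kb. The gene midpoint, genes of up to 10 kb, loci merged under 100 kb, leaving out each list's leading chromosome, rotation for the domain correlation and the matched lists were chosen after seeing the data. Chance was measured by rotation: all boundaries of a chromosome were shifted together by a random amount round its annotated span, from its first to its last gene or boundary, 100000 times. The plan was to rotate round non-gap sequence, but gaps were not known without a genome sequence. Rotated boundaries could therefore fall in gaps. Two-sided p-values of the list, locus and matched tests and of boundaries inside genes are double the smaller tail. List p-values were adjusted by the Benjamini-Hochberg method over the 24 lists, each with at least 10 located genes, at a threshold of 0.05. Correlations were tested by permutation with 100000 resamples, two-sided by the absolute value of the coefficient, and by rotation from the distance to the rotation mean. Domains over 5 Mb were left out of the domain correlation. Matched lists were drawn within strata of 5 classes of protein-coding neighbours within 500 kb and 5 classes of gene length. The number of these draws was raised to 100000 after the zinc finger list had given an adjusted p on either side of 0.05 in 2 smaller sets of draws.

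Genes were named by a fixed rule. All pluripotency and epiblast-like genes could be named, Rad21, Ctcf, Ep300 and Crebbp always were, and other lists gave at most 4 genes near a boundary in alphabetical order. The 5 longest and 5 shortest domains were described with their genes, and since 7 domains tie as shortest, examples were taken from all 7.

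The tests were tested on simulated data. In 20 sets of randomly rotated boundaries, 3.33% of 480 list tests had an unadjusted p under 0.05 and 0 passed after adjustment. These sets follow the test's own model of chance, so they check its computation and not whether rotation suits real boundaries. With boundaries planted at 30% of the ribosomal protein or proteasome genes, both lists passed in 20 of 20 sets by rotation and by local shifts. Matched lists without a difference gave p under 0.05 in 5% of 100 runs, and rank correlations in 5%. Planted differences were found in 100% of runs for each. Genes and values were independent in the matched and correlation runs. These runs therefore do not show how the tests behave with clustered genes or neighbouring domains.

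CTCF motifs, motif orientation and GC content were not analysed here because no genome sequence was used, and the limit on gap sequence in domains was not applied for that reason. Boundary strength was not analysed because the list has no score. A comparison meant to test whether reads can be placed in near-identical gene copies was dropped: histone and tRNA genes are short beside a 25 kb interval, so their boundaries say nothing of megabase receptor arrays. Mappability was not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.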

Results

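Micro-C, a chromosome conformation assay in which chromatin is cut with micrococcal nuclease, was applied to mouse cells in the G1 phase. The 26 libraries fall into 5 groups. Embryonic stem cells (ESCs) carrying a degradable tag on the cohesin subunit RAD21 received 0.05% v/v DMSO as vehicle (6 libraries), 500 nM dTAG to degrade RAD21 (6 libraries) or 20 µM A485, an inhibitor of the acetyltransferases p300 and CBP (6 libraries). In replicates 4 to 6 of the dTAG and A485 groups the growth protocol mentions epiblast-like cells (EpiLCs) although the cell type is given as ESC, and these libraries enter no test. EpiLCs received DMSO (4 libraries) or dTAG (4 libraries). The processed data used here are a single list of domain boundaries made from the 6 DMSO-treated ESC libraries pooled. Comparisons between treatments or between cell types were not analysed here, and the list carries no replicate error. The number of contacts behind each boundary is unknown, and the intervals given for shares cover counting error only.

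The genome of DMSO-treated ESCs was divided by 3515 boundaries, each an interval of 25 kb in mm10 coordinates, on chromosomes 1 to 19 and X. The list held 1.37 boundaries per Mb of annotated span. Chromosome 19 was the most densely divided, at 1.61 per Mb, and chromosome X the least, at 1.04 per Mb. Among the autosomes chromosome 14 was the sparsest, at 1.15 per Mb, and its first boundary lay at 11525001, after 8.53 Mb that held 91 protein-coding genes and 61 pseudogenes. Across the 19 autosomes, boundary density and protein-coding gene density were not detectably related (Pearson's r 0.284, permutation p 0.237, and Spearman's rho 0.256, permutation p 0.288, both two-sided). Without chromosomes 11 and 7, the autosomes farthest from the median gene density, r was 0.372 (permutation p 0.141). None of the 6 correlations computed passed, and the smallest adjusted p was 0.451.

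The 3495 domains between neighbouring boundaries had a median length of 500 kb, with quartiles of 325 and 825 kb, and 81.1% were shorter than 1 Mb. The longest, 12 Mb on chromosome X from 23825001 to 35825000, held 51 protein-coding genes, among them Slx and members of the Btbd35f and Spin2 families, and 54 pseudogenes. A 6.08 Mb domain on chromosome 1, from 97700001 to 103775000, held only 6 protein-coding genes, including Pam and Cntnap5b. Chromosome 7 contributed a 5.83 Mb domain with 64 protein-coding genes, 47 of them vomeronasal receptor genes, and a 5.23 Mb domain with 160, of which 86 were vomeronasal receptor genes. The remaining member of the 5 longest, 5.68 Mb on chromosome X, held 9 protein-coding genes, including Tgif2lx1 and Tgif2lx2, with Pcdh11x at its edge. Gap sequence was not excluded and mappability was not tested, so whether boundaries could be called throughout these long stretches is unknown. At the other end, 7 domains measured 125 kb. Examples are the Phyh, Ucma and Mcm10 domain on chromosome 2 and the Ccl22, Cx3cl1 and Ccl17 domain on chromosome 8. Another, on chromosome 13, held 7 protein-coding genes, 5 of them histone genes.

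**Figure D1:**
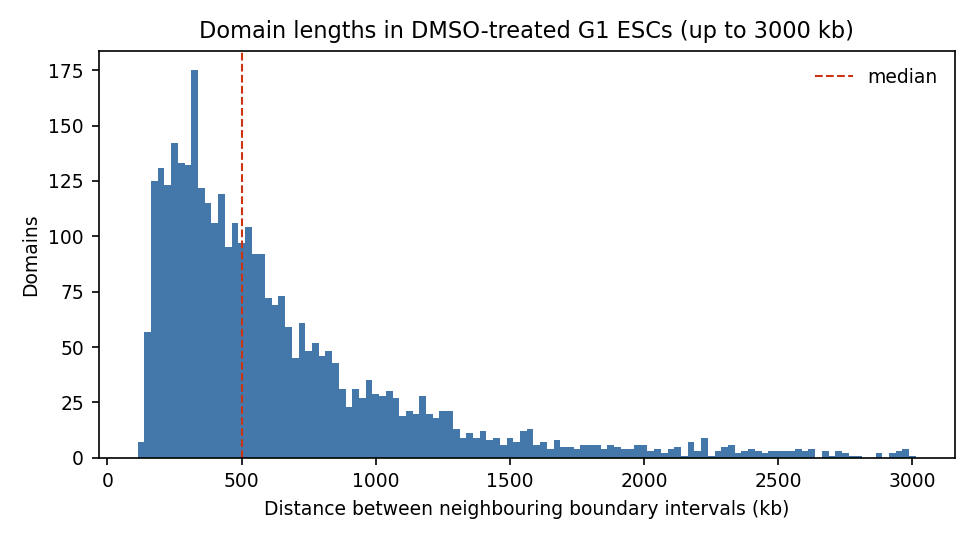
Number of domains (vertical axis) by length in kb (horizontal axis, bins of 25 kb, up to 3000 kb) in the pooled list. The dashed line marks the median of 500 kb, and the most common length was 325 kb, with 175 domains.

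Among domains of up to 5 Mb, long ones tended to be poorer in protein-coding genes than short ones. The 5.23 Mb domain on chromosome 7, above that limit, was not, at 3.06 per 100 kb. The 873 shortest domains held 1.21 protein-coding genes per 100 kb and the 873 longest 0.561. Across 3490 domains of up to 5 Mb, length and gene density were inversely related (Spearman's rho -0.327, two-sided permutation p 1e-05, the smallest the draws can give). Domains are not independent replicates, and rho is taken across domains within 1 pooled list. When the boundaries were instead rotated along their chromosomes, a test chosen after seeing the data, rho averaged 0.0894 with an SD of 0.0195, and the two-sided p was 0.000999, the smallest that 1000 rotations can give.

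Domain boundaries coincided with gene ends far more often than randomly placed ones. Of the 3515 boundaries, 2261 had an end of a protein-coding gene inside them or within 10 kb, a share of 64.3% (95% Wilson interval 62.7 to 65.9). Rotating all boundaries of a chromosome together gave 35.0% on average (middle 95% 33.5 to 36.5), so the observed share was 1.84-fold higher (one-sided p 1e-05, the smallest the draws can give). Counted by gene, 3935 of 21521 protein-coding genes (18.3%) lay this close, against 9.21% by rotation, a ratio of 1.99. Gene ends peaked in the boundary interval itself, at 0.884 per 25 kb against a genome mean of 0.419, and the ratio to that mean fell from 2.11 there to 1.13 and 1.15 at 100 kb on either side. It stayed above the genome mean out to 1000 kb on either side (lowest 1.06), so the wider surroundings of boundaries were also rich in gene ends. When each boundary was instead moved by 100 to 500 kb, 40.9% had a gene end. The observed share was 1.57-fold that local background (one-sided p 1e-05 by these local shifts). The annotation used gives no strand, so promoters were not separated from the other end of the gene.

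**Figure D2:**
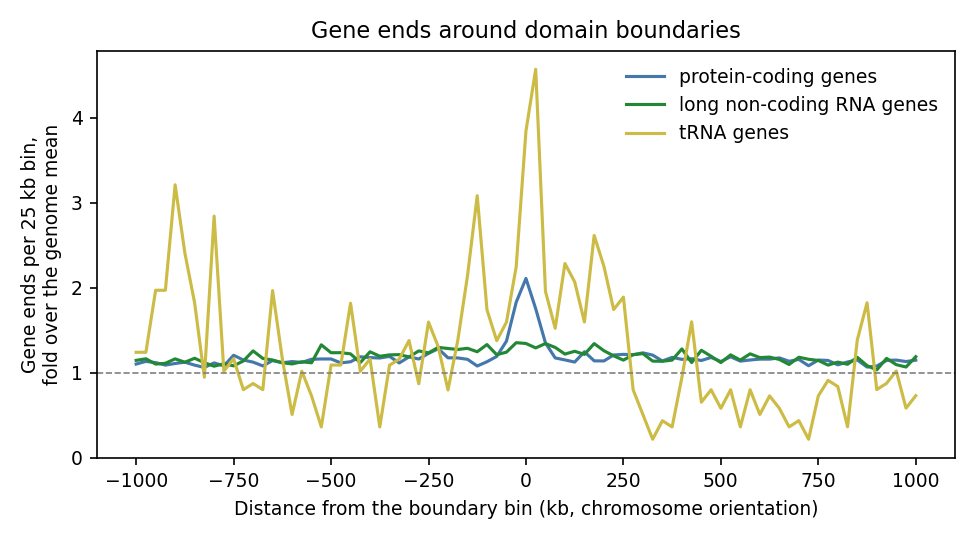
Gene ends per 25 kb bin, as fold over the genome mean (vertical axis), by distance from the boundary in kb (horizontal axis), for protein-coding, long non-coding RNA and tRNA genes. Protein-coding gene ends reached 2.11-fold at the boundary. The tRNA line is uneven because these genes are few and clustered.

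The main pluripotency genes lay inside domains rather than at their boundaries, as most genes did. The midpoints of 19750 of 21521 protein-coding genes lay in a domain. Sox2 lay 24.995 kb from a boundary in a 175 kb domain on chromosome 3 that held no other protein-coding gene. Pou5f1 lay 56.0 kb from a boundary in a 450 kb domain on chromosome 17. Nanog, 160.4 kb from a boundary, shared a 575 kb domain on chromosome 6 with Dppa3. Dppa2 and Dppa4 shared an 800 kb domain on chromosome 16. Klf4, Klf2, Esrrb and Prdm14 lay 252, 244, 153 and 223 kb from a boundary, and Tfcp2l1 and Zfp42 lay 103 and 43.0 kb from one. Of the 31 genes of the pluripotency list, only Tet1 had an end within 10 kb, inside the boundary at 62800001 on chromosome 10. That share, 3.23%, was 0.418-fold the rotation mean of 7.72% and did not pass (two-sided adjusted p 0.654). Rotation left 0 to 19.4% of the list near a boundary in its middle 95%, so a deficit was not detectable with this list. With a window of 50 kb the direction turned, with 22.6% near against 20.1% by rotation (1.13-fold, adjusted p 0.867, range over the alternatives 0.246 to 1).

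**Figure D3:**
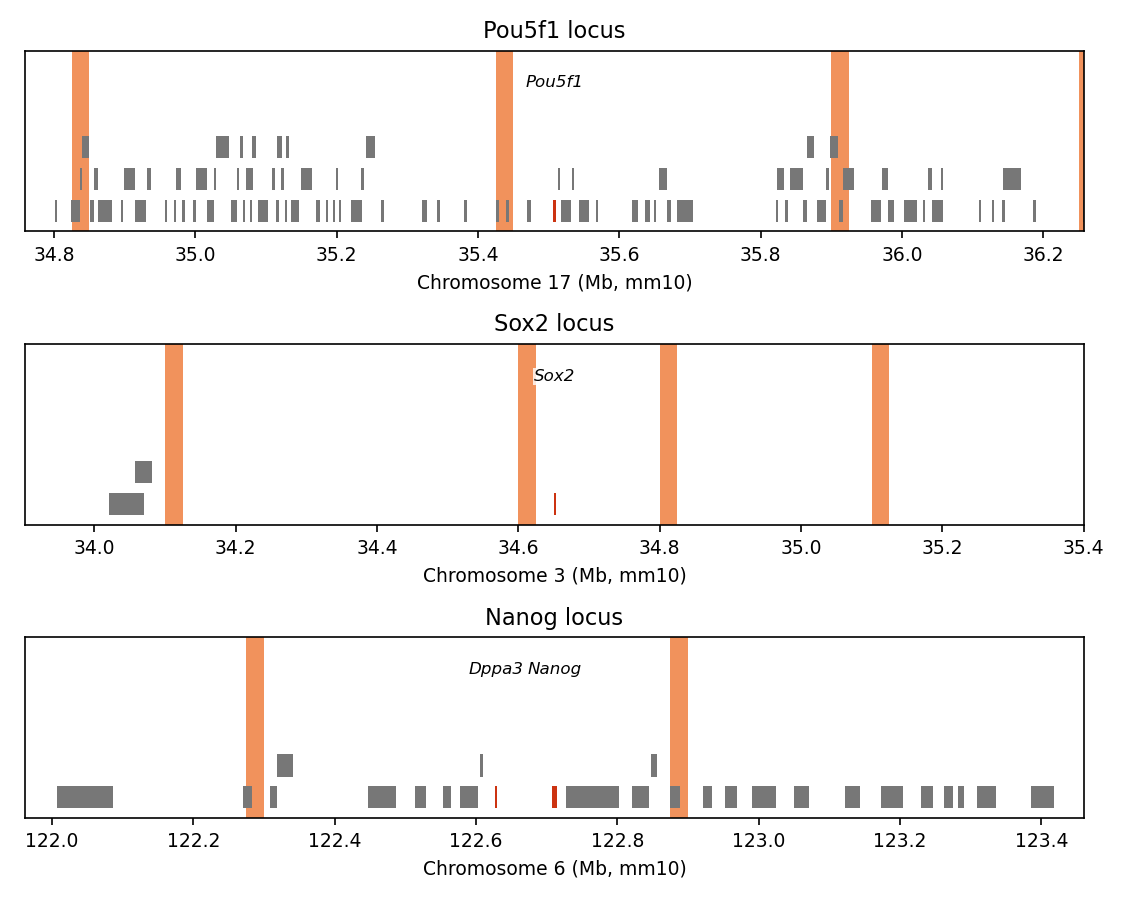
Maps of 1500 kb around Pou5f1, Sox2 and Nanog (horizontal axes in Mb, mm10). Orange bands are boundary intervals, grey bars protein-coding genes and red bars genes of the pluripotency list. Vertical position only keeps overlapping genes apart.

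Among genes of the epiblast-like and primed state, Dnmt3b and Grhl2 had an end inside a boundary and Fgf8 lay 7.06 kb from one. Pou3f1, Sall2, Fgf15 and Nodal lay between 14.3 and 24.7 kb away, and Otx2, Sox3 and Fgf5 lay 282, 232 and 54.2 kb away. Fgf15 shared its 475 kb domain on chromosome 7 with Fgf4 of the pluripotency list, and the boundary that closes this domain holds Ccnd1. Within 10 kb were 3 of the 20 genes, 1.89-fold the rotation mean (adjusted p 0.503). With a window of 50 kb the list passed, at 2.26-fold (adjusted p 0.0285, range over the alternatives 0.0285 to 1), whereas with gene midpoints the direction turned (0.831-fold).

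The genes whose products the treatments target lay inside domains, as did the midpoints of 19750 of all 21521 protein-coding genes. Rad21, which encodes the degraded cohesin subunit, lay 37.6 kb from a boundary in a 550 kb domain on chromosome 15. Ep300 and Crebbp, which encode p300 and CBP, lay 161 and 256 kb from a boundary. Ctcf, which encodes the insulator protein that halts cohesin, lay 311 kb away in a 1350 kb domain on chromosome 8. Other genes of the lists that hold these genes did sit at boundaries. The cohesin, CTCF and condensin list also holds genes outside these classes, such as Ldb1. Of its 25 genes, 9 were within 10 kb of a boundary, including Esco2, Hdac8, Ldb1 and Pds5b. This was 3.40-fold the rotation mean (adjusted p 0.00426). Several of the 9 near genes lie outside the named classes, and neither Ctcf nor the condensin genes were among the 9. The list did not pass with no window (adjusted p 0.0773, the highest of its alternatives, from 0.00316). The acetyltransferase, BET and Mediator list also holds a gene of another kind, Brd9. Of its 21 genes, 8 were within 10 kb of a boundary, including Brd3, Brd9, Kat2b and Kat6a, 3.49-fold (adjusted p 0.00514). That call was lost in 4 of 8 alternatives, including both other windows, with adjusted p from 0.0033 to 0.424.

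Of the 24 gene lists tested by rotation, 14 lay near boundaries more often than chance, 2 less often, and 8 did not pass. Protein-coding genes as a whole had a ratio of 1.99, so a list above chance need not differ from other genes. Cytoplasmic ribosomal protein genes, including Rpl10a, Rpl13, Rpl17 and Rpl18, were near a boundary in 28 of 84 cases (33.3%, Wilson interval 24.2 to 43.9), 5.05-fold (adjusted p 0.00012). Proteasome genes, including Psma1, Psma2, Psmb1 and Psmc1, were near in 13 of 39 cases, 4.04-fold (adjusted p 0.000192), but did not pass among genes of up to 10 kb (1.76-fold, adjusted p 0.832, the highest of its alternatives, from 8e-05). Mitochondrial ribosomal protein genes, such as Mrpl11 and Mrpl15, reached 2.93-fold (adjusted p 0.000343). With a window of 50 kb the ratios were smaller, 2.90 for cytoplasmic and 1.66 for mitochondrial ribosomal protein genes (adjusted p 9.6e-05 and 0.0174). Genes with an Eif symbol, mainly translation initiation factors such as Eif1 and Eif2s1 but also their kinases and binding proteins, reached 2.38-fold (adjusted p 0.0139). The Eif list did not pass without chromosome 15 (2.00-fold, adjusted p 0.0939) or among genes of up to 10 kb (1.52-fold, adjusted p 0.898), and its adjusted p ranged from 0.0021 to 0.898. Genes of up to 10 kb are only a part of the proteasome and Eif lists, so an excess could go undetected there. Immediate early and G1 genes were near in 6 of 24 cases, 3.24-fold (adjusted p 0.0268), with Ccnd1, Ccnd2 and Ier2 ending inside a boundary and Cdk4 at 7.71 kb. This call was lost in 4 of 9 alternatives, with adjusted p from 0.0127 to 0.127. Germ layer and lineage genes, including Hand2, Meis1, Lhx5 and Epha4, were near in 6 of 32 cases, 2.18-fold, and did not pass (adjusted p 0.139). With a window of 50 kb, 50% of them were near against 20.4% by rotation, and the list passed at 2.45-fold (adjusted p 0.00096, range over the alternatives 0.00096 to 1), whereas with no window the direction turned (0.662-fold).

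**Figure D4:**
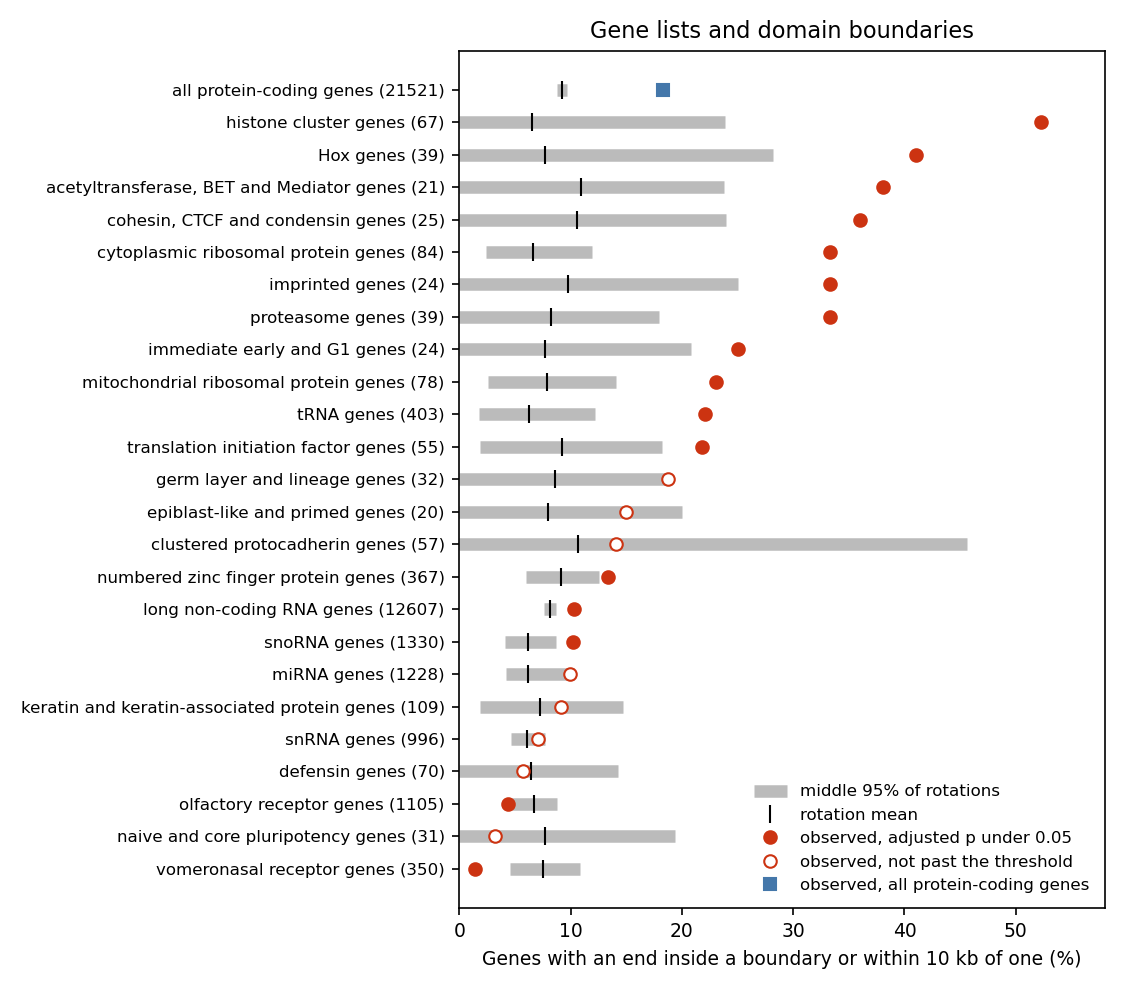
Percent of each list's genes with an end inside a boundary or within 10 kb (horizontal axis), with the number of genes in brackets. Grey bars and ticks give the middle 95% and the mean of 100000 rotations. Filled red points passed at an adjusted p under 0.05 and open ones did not. Histone genes were highest, at 52.2%, and vomeronasal receptor genes lowest, at 1.43%.

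Hox clusters were divided by boundaries, and many histone genes lay close to one. Each of the 4 Hox clusters contained 1 boundary, and 16 of 39 Hox genes were near it, 5.36-fold (adjusted p 0.00694). In HoxA the boundary at 52225001 held Hoxa9, Hoxa10 and Hoxa11, with Hoxa13 8.85 kb beyond it and Hoxa7 6.43 kb away on the opposite side. In HoxD the boundary at 74675001 held Hoxd9 to Hoxd12, with Hoxd13 on one side and Hoxd1, Hoxd3, Hoxd4 and Hoxd8 on the other. In HoxB it held Hoxb9 and separated Hoxb13 from Hoxb1 to Hoxb8. In HoxC it held Hoxc12, and Hoxc13 crossed its edge, with the other 7 genes on the opposite side. Genes are called held by a boundary here by their midpoints. The Hox genes beyond Hoxa7, Hoxa10, Hoxa11 and Hoxa13 were named after their values were seen. Counted by cluster, rotation placed a boundary near 23.6% of such loci (two-sided p 0.00558). Histone genes were near in 35 of 67 cases, 8.003-fold (adjusted p 0.00024), of which 29 lay on chromosome 13, where H1f1 and H1f3 ended inside boundaries. The ratio was 4.54 against the local background, which moves each boundary by 100 to 500 kb (adjusted p 0.000576), and 3.42 counted by locus (4 of 9 loci, two-sided p 0.0363, unadjusted). Without chromosome 13 the remaining 14 histone genes did not pass (6.71-fold, adjusted p 0.179), and without chromosome 2 the Hox genes did not (4.39-fold, adjusted p 0.0604).

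**Figure D5:**
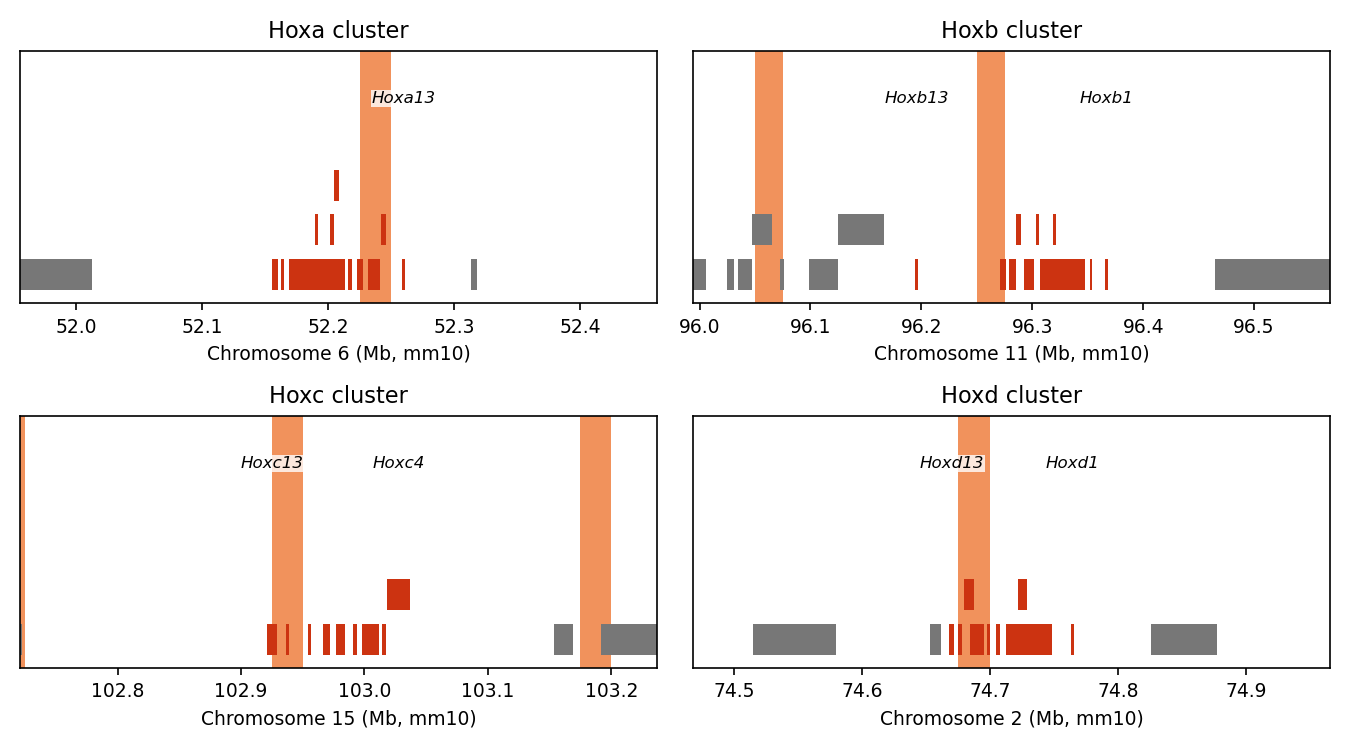
Maps of the 4 Hox clusters with 200 kb on either side (horizontal axes in Mb, mm10). Orange bands are boundary intervals, red bars Hox genes and grey bars other protein-coding genes. Each cluster contains 1 boundary, toward the end that carries its group 13 gene.

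Imprinted genes, expressed from a single parental allele, were near boundaries in 8 of 24 cases, 3.40-fold (adjusted p 0.0072). Igf2r, Impact and Mkrn3 lay 7.41, 7.05 and 4.85 kb from a boundary, and Kcnq1 ended inside one. Of the 8, 5 lay on chromosome 7, and without that chromosome the ratio was 2.23 (adjusted p 0.368). The call was also lost with no window (2.21-fold) and with gene midpoints (3.15-fold), and the adjusted p ranged from 0.00272 to 0.424. Some neighbouring imprinted genes, named after their values were seen, shared a domain and others did not, which was not tested. H19 and Igf2 shared 400 kb, Cdkn1c and Kcnq1ot1 shared 350 kb with Kcnq1, and Dlk1, Meg3 and Rian shared 575 kb. Snrpn and Ube3a lay in a 2950 kb domain separate from the 225 kb domain of Mkrn3 and Ndn. Phlda2, in a domain that begins at 143500001, was separated by a boundary from Cdkn1c, whose domain ends at 143475000.

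Differences between classes of non-coding RNA genes were not tested. All annotated genes together had a ratio of 1.61, so a class above chance need not differ from other genes. tRNA genes were near a boundary in 89 of 403 cases, 3.53-fold (adjusted p 0.00012), including n-TAagc7 and n-TAagc12 on chromosome 13. snoRNA genes reached 1.65-fold (adjusted p 0.00464), though not past the threshold at a window of 50 kb (1.26-fold, adjusted p 0.143, range from 0.000229), and long non-coding RNA genes 1.26-fold (adjusted p 0.00012). miRNA genes, at 1.61-fold (adjusted p 0.0971), and snRNA genes, at 1.15-fold (adjusted p 0.339), did not pass. miRNA genes did pass when neighbours under 100 kb apart counted as 1 locus, with 100 of 831 loci near, 1.72-fold (adjusted p 8e-05, range over the alternatives 8e-05 to 0.325).

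Vomeronasal receptor genes lay away from boundaries. Only 5 of 350 vomeronasal receptor genes were near one, among them Vmn1r1, Vmn1r4, Vmn1r32 and Vmn1r223, 0.190-fold the rotation mean (adjusted p 0.00012). Olfactory receptor genes were near in 48 of 1105 cases, 0.647-fold (adjusted p 0.0326), but this call was lost in 5 of 9 alternatives, including no window (0.818-fold), the local background (0.785-fold) and counting by locus (0.821-fold), with adjusted p from 0.00764 to 0.428. Median distances to a boundary were 419 kb for vomeronasal and 254 kb for olfactory receptor genes, against 98.9 kb for all protein-coding genes. Numbered zinc finger protein genes, including Zfp110 and Zfp120, were slightly above chance, at 1.46-fold (adjusted p 0.0326), but did not pass on the autosomes alone (1.42-fold, adjusted p 0.0532) or among genes of up to 10 kb (1.28-fold, adjusted p 0.886), with a range from 0.00355. Clustered protocadherin genes (1.32-fold, adjusted p 0.651), keratin genes (1.26-fold, adjusted p 0.66) and defensin genes (0.885-fold, adjusted p 1) did not pass.

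Set against other protein-coding genes rather than random positions, few lists stood apart. This comparison, chosen after the rotation results were seen, drew 100000 random lists matched on local gene density and gene length for 19 lists. Ribosomal protein genes exceeded it, with 28 near against a middle 95% of 5 to 16, as did Hox genes (16 against 1 to 9) and histone genes (35 against 2 to 11), each with a two-sided p of 2e-05, the smallest these draws can give, and an adjusted p of 7.6e-05. Vomeronasal (5 against 37 to 61) and olfactory receptor genes (48 against 90 to 122) fell below it at that adjusted p. Zinc finger genes, above random positions, were below their matched genes (49 against 53 to 81, adjusted p 0.0474), close enough to the threshold for a repeat of the draws to change the call. Proteasome genes (13 against 3 to 12, adjusted p 0.0759), the acetyltransferase group (8 against 1 to 7, adjusted p 0.0981) and pluripotency genes (1 against 2 to 10, adjusted p 0.0599) did not pass the adjustment. Lists above random positions but inside their matched range were mitochondrial ribosomal protein genes (18 against 7 to 19), cohesin, CTCF and condensin genes (9 against 2 to 10), Eif genes (12 against 5 to 16), immediate early and G1 genes (6 against 1 to 7) and imprinted genes (8 against 1 to 8). Of the imprinted list, only the 20 protein-coding genes entered this comparison. Genes count as independent here, which overstates the evidence for clustered families such as Hox, histone and receptor genes.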

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

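Gene midpoints, genes of up to 10 kb, merged loci, rotation for the domain correlation and leaving out a list's leading chromosome were chosen after seeing the data. No paired analysis was possible because 1 pooled list was used, without values per replicate. The share of boundaries with a protein-coding gene end stayed above chance in every alternative run, from 1.39-fold with all annotated genes to 1.98-fold with no window, and the inverse relation of domain length and gene density held at -0.272 for domains of up to 2 Mb. The count of 16 lists past the threshold was 11 with no window, 16 at 50 kb (14 of them shared) and 14 with the local background. It was 15 on autosomes, 13 with midpoints and 14 by locus (13 shared). By locus, Hox, histone, protocadherin and defensin genes formed fewer than 10 loci and got no adjusted p. Hox and histone genes therefore could not count there, and their unadjusted locus p-values are given above. The count fell to 8 with genes of up to 10 kb, all among the 16. There cohesin, acetyltransferase and imprinted genes were too few to test. The count was 10, all among the 16, without the chromosome holding most of a list's near genes. Ribosomal, mitochondrial ribosomal, tRNA, long non-coding RNA and vomeronasal genes passed in all 9 settings. For long non-coding RNA genes the ratio was only 1.10 with the local background. Not every setting was a separate check. Merging boundaries under 50 kb apart gave the main ratios for every list. Midpoints and genes of up to 10 kb left the tRNA ratio at 3.53. Leaving out the chromosome with most near genes favours a deficit, as for vomeronasal (0.139-fold) and olfactory receptor genes (0.523-fold). Olfactory receptor genes lost their call in 5 of 9 settings, the acetyltransferase and the immediate early groups in 4 each, imprinted genes in 3, Eif and zinc finger genes in 2 each, and Hox, histone, cohesin, proteasome and snoRNA genes in 1 each. Calls were gained at 50 kb by germ layer genes (2.45-fold) and primed genes (2.26-fold), and by miRNA genes counted by locus (1.72-fold). Directions reversed only for lists that had not passed: germ layer genes with no window (0.662-fold), pluripotency genes at 50 kb (1.13-fold), protocadherins with the local background (0.795), midpoints (0.248) and genes of up to 10 kb (0.626), defensins with the local background (1.43), primed genes with midpoints (0.831) and keratins without chromosome 11 (0.925). The cause was not tested. Merging boundaries under 50 kb apart changed nothing, since none are that close. Alternatives on motifs, GC content, boundary score and transcript start sites were not run. Unknown depth leaves open how many weaker boundaries the list misses.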

Other observations

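The matched comparison of vomeronasal genes, the counts of boundaries inside genes, the spacing comparison and the protocadherin description below were chosen after the results were seen. The matched tests of ribosomal, proteasome and pluripotency genes and the locus test were set before those tests were run but after the rotation results were known.

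The ribosomal protein genes, near boundaries or not, lie among more genes than usual (median 20.5 protein-coding neighbours within 500 kb against 16 for all protein-coding genes), which might bring their ends close to boundaries. Random lists matched on local gene density and gene length had 5 to 16 genes near a boundary in their middle 95%, against 28 observed, which argues against that explanation as the whole cause. For proteasome genes the count of 13 lay just above the matched range of 3 to 12 and failed adjustment (adjusted p 0.0759), so neighbourhood and length remain open there. Transcription was not measured here, and no biological explanation was tested.

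Pluripotency genes were seldom near boundaries, with 1 of 31 against a matched range of 2 to 10 (p 0.0221). A gene-poor setting (median 6 neighbours) may not account for all of it, but the result failed adjustment over the lists (0.0599). Rotation gave 0.418-fold and could not detect a deficit in a list of this size, so it decides nothing. At a window of 50 kb the ratio was 1.13, not distinguishable from chance (adjusted p 0.867). The pattern itself is thus unsettled, and no biological explanation was tested.

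Vomeronasal receptor genes avoided boundaries, and a few large arrays could produce this. Counting neighbours under 100 kb apart as 1 locus left 5 of 83 loci near a boundary, 0.260-fold, with a two-sided rotation p of 4.00e-05. This argues against groups of genes under 100 kb apart as the whole cause. A large array can split into several such loci, and no run left out the largest arrays, so they stay open as a cause. Lists matched on classes of gene density and gene length had 48.7 genes near on average, against 5 observed. Their range of 37 to 61 counts clustered genes as independent and is too narrow, so these explanations were not excluded. Poor read placement in near-identical copies was not tested and stays open as a technical explanation, and no biological explanation was tested.

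Boundaries lay wholly inside a protein-coding gene in 776 cases, 22.1% of the list, against 27.6% by rotation (0.801-fold, two-sided p 2e-05, the smallest the draws can give). For genes of at least 200 kb the count was 333, or 9.47% against 15.4% (0.613-fold, at that same p). These shares are not independent of the excess of gene ends, since 49.2% of boundaries held a protein-coding gene end against 24.8% by rotation, which leaves fewer to lie inside a gene. They are not evidence that boundaries avoid the inside of genes.

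No domain was shorter than 125 kb, whereas boundaries placed at random would give 558 such domains. The boundary caller's settings are not given in the sources used here.

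The protocadherin array on chromosome 18 held 2 boundaries, described here by gene midpoints. The 14 alpha genes lay in a 450 kb domain, 21 beta genes in a 400 kb domain and the midpoints of 21 gamma genes in a 250 kb domain, with Pcdhb1 in the boundary at 37250001 between the alpha and beta genes. The boundary at 37675001 lay within the start of the gamma array. Pcdhga1, Pcdhga2 and Pcdhga3 have their lower coordinate before it and cross it, and Pcdhga4, Pcdhga5, Pcdhgb1 and Pcdhgb2 have theirs inside it. Counted by locus, 2 of 2 were near a boundary against 49.7% by rotation (two-sided p 0.508). This is the highest count possible, so the test could not detect an excess and decides nothing. Placement relative to the subfamilies was not tested.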
